A study of Homo sapiens with 5 samples.

How the data were processed

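Ribose methylation of ribosomal RNA was measured by RiboMethSeq in 5 libraries of PaTu cells, 1 each labelled Mock, SCR and ADAR2 #1 and 2 labelled ADAR1. Per the labels' protocols, total RNA was purified, treated with DNase, hydrolysed in bicarbonate buffer, end-repaired and made into libraries with a small RNA kit. Per the submitters' processing notes, Trimmomatic 0.39, FastQC 0.11.9, Bowtie2 2.3.5.1 and SAMtools 1.15.1 were used. Their settings, the rRNA reference sequence and the formula of the methylation score are not given in the sources used here.

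The authors deposited 1 table with a methylation level per position and library, a fraction between 0 and 1, for 110 positions. As usually computed, a RiboMethSeq score compares the fragment ends at a position with those at its flanking positions in the same library, so it is set within each library and needs no scaling between libraries. It depends on the flanking window, and close methylated positions can affect each other's score. Exact zeros in the table may be scores bounded at 0. The table gives no read counts, so the depth of each library and the counting error of each level are unknown and no counting intervals are given. All 5 columns carried a sample's title, and 0 columns were left unmatched. Positions are named by rRNA and nucleotide number, without the nucleotide or the guide snoRNA. The lists of positions were those of each rRNA, the 5′ and 3′ parts of 18S and of 28S (divided at position 2500), partly and fully methylated positions, and positions with and without another listed position within 6 nucleotides. The lists by nucleotide and by guide that had been planned were therefore not analysed here, and the guides named in the report are background knowledge. Genome coordinates were not used here.

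Levels were used as deposited. Mock and SCR were pooled as the reference because they are the only libraries not labelled with an ADAR gene, and their difference counts as spread. In R 4.3.3, limma 3.58.1 was fitted to all 5 libraries with 3 groups (reference, ADAR1, ADAR2), which leaves 2 residual degrees of freedom, and eBayes with a trend on the mean level added a prior worth 3.41. The contrasts were ADAR1 minus reference, ADAR2 minus reference and ADAR1 minus ADAR2. Tests were two-sided with Benjamini-Hochberg adjustment over 110 positions and a threshold of 0.05. Intervals are 95% intervals of the moderated test. Lists of at least 3 positions were tested with fry and with camera, with a preset correlation of 0.01 and with an estimated one, and adjusted over the 10 lists of a comparison. No p-value is attached to a correlation, because positions are not independent replicates. Camera and the ranges of shuffled positions take positions as units, so they are not tests over replicate libraries. The correlation of effects was set beside 1000 simulations with no effect that shared the reference libraries. Every simulated library, the reference included, had the moderated residual spread of its position.

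Positions were named by a rule written before the data were examined: every position past the threshold, then the 10 largest differences in each direction (for ADAR1 only where both libraries lay outside the reference values on the same side, for ADAR2 where the library did, and for ADAR1 against ADAR2 without this condition), the 5 positions with the lowest mean level, the 5 with the largest difference between Mock and SCR, and both 5.8S positions. Positions 4637, 4523 and 4498 of 28S and 683 of 18S, and the positions where ADAR1 and ADAR2 lay on opposite sides of the reference, were named after their values were seen.

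The tests were tried on simulated data with the real mean levels, 110 positions and 20 changed positions for the ADAR1 comparison. With the moderated residual spread of the data, 52.6% of falls of 0.05, 84.9% of falls of 0.1 and 96.4% of falls of 0.2 were recovered. With no change, 25% of the simulations gave at least 1 false call. With the spread between Mock and SCR, set to a common value for all positions, the recovery of a fall of 0.05 was 94.2%. There 4% of simulations with no change gave a false call. The real difference between Mock and SCR varied by position, so this recovery need not hold at each one. The changed positions were drawn without those of the lowest mean levels. Alternatives were no variance trend, a robust trend, the logit of the level (bounded at 0.01 and 0.99), positions with a mean of at least 0.5, median-centred libraries, an adjusted p of 0.1, fits of the compared groups alone, size limits of 0.02 and 0.1, and each library left out in turn. The labels name no batch, date or lane. Figures were drawn with matplotlib 3.10.9.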

Results

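The data gave the level of ribose 2′-O-methylation at 110 positions of human ribosomal RNA in 5 RiboMethSeq libraries from PaTu cells, a name carried by established lines of human pancreatic cancer cells. RiboMethSeq fragments RNA in alkaline buffer and counts the ends of the fragments. A methyl group on the ribose protects the bond that follows it, so a methylated position has few ends compared with its neighbours. Most of these methyl groups are placed by fibrillarin, guided by box C/D small nucleolar RNAs (snoRNAs). The table covered 41 positions of 18S rRNA, 2 of 5.8S rRNA and 67 of 28S rRNA. These rRNAs are transcribed from repeated ribosomal DNA arrays, and positions are given as in the deposited table, counted along each mature rRNA. Of the 5 libraries, 2 were labelled ADAR1 (#1 and #2), 1 was labelled ADAR2 #1, and the others were labelled Mock and SCR. ADAR1 and ADAR2 are the adenosine deaminases that convert adenosine to inosine in double-stranded RNA. The labels do not state how the 2 genes were manipulated, nor whether #1 and #2 mark repeat cultures or different reagents. Mock and SCR served together as the reference (2 libraries). Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The table holds levels without read counts, so the depth behind each value is unknown.

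Most positions were highly methylated in every library. The median level over the 110 positions was 0.885 in Mock, 0.888 in SCR, 0.883 in ADAR1 #1, 0.897 in ADAR1 #2 and 0.887 in ADAR2 #1, on a scale from 0 to 1. Averaged over the libraries, 48 positions had a level of at least 0.9 and 6 a level below 0.5. The lowest of these were 18S position 1440 (mean 0.0408), 18S position 354 (0.0537) and 18S position 1447 (0.154), followed by 28S position 3867 (0.470) and 28S position 2861 (0.484). Position 1440 of 18S was listed at 0 in Mock, SCR and ADAR1 #1, at 0.120 in ADAR1 #2 and at 0.0839 in ADAR2 #1. Position 354 of 18S was at 0.226 in ADAR1 #1 and 0.0427 in Mock, and was listed at 0 in the other 3 libraries.

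Mock and SCR gave nearly the same profile. Their root mean square difference was 0.0155 over the 110 positions, and only 28S position 1323 differed by at least 0.05 (0.431 in Mock and 0.485 in SCR). The next largest differences between them were at 28S position 2861 (0.489 and 0.539), 28S position 2415 (0.483 and 0.530), 18S position 1272 (0.718 and 0.765) and 18S position 428 (0.717 and 0.764). By root mean square, the 2 ADAR1 libraries differed more from each other than either did from Mock or SCR. Their difference was 0.0594, with 19 positions differing by at least 0.05, whereas ADAR1 #1 lay 0.0457 from Mock and 0.0491 from SCR and ADAR1 #2 lay 0.0492 from Mock and 0.0456 from SCR. By the median absolute difference this order did not hold, with 0.0162 between the ADAR1 libraries and 0.0191 between Mock and ADAR1 #2. ADAR1 #2 was closest to ADAR2 #1, at 0.0266. ADAR1 #1 and ADAR2 #1 were the most distant pair, at 0.0672. Without the positions with a mean level below 0.5, the 2 ADAR1 libraries still differed by 0.0545 and Mock and SCR by 0.0129.

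**Figure D1:**
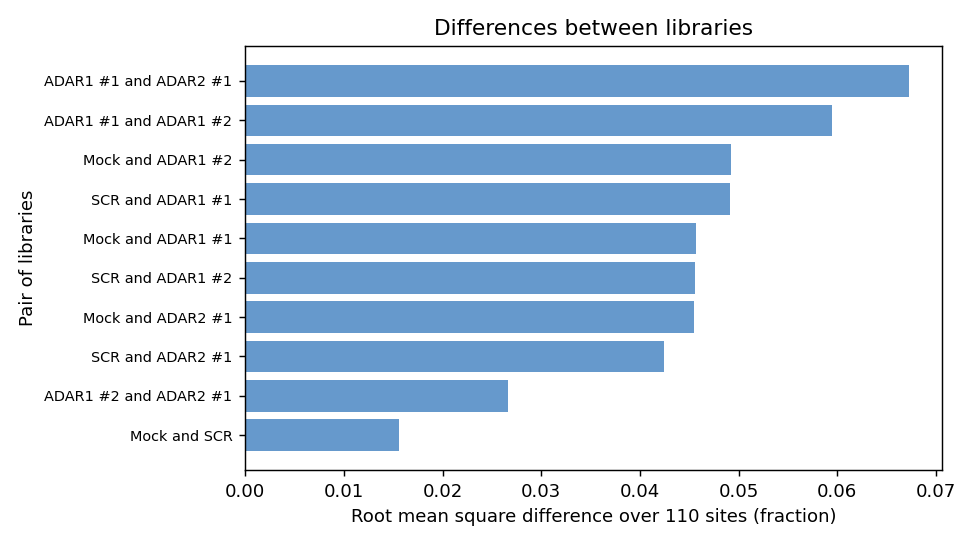
Root mean square difference in methylation level (fraction) over 110 rRNA positions for each pair of libraries, 1 bar per pair. Mock and SCR are the closest pair at 0.0155, followed by ADAR1 #2 and ADAR2 #1 at 0.0266, and the 2 ADAR1 libraries are 0.0594 apart.

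The first comparison asked whether rRNA methylation differed between the ADAR1 libraries and the reference. No position passed the test. Levels above both Mock and SCR were seen in both ADAR1 libraries at 28S position 3867, with 0.551 ± 0.0034 (SD, n = 2) against 0.432 in Mock and 0.399 in SCR, and at 28S position 4590, with 0.844 ± 0.012 (SD, n = 2) against 0.748 and 0.770. At 18S position 436, a target of SNORD100, the ADAR1 libraries averaged 0.761 ± 0.012 (SD, n = 2) against 0.672 in Mock and 0.705 in SCR. At 28S position 3792 they averaged 0.9503 ± 0.015 (SD, n = 2) against 0.902 and 0.893. The lowest relative levels were at 18S position 627, a target of SNORD65, with 0.485 in ADAR1 #1 and 0.649 in ADAR1 #2 against 0.704 in Mock and 0.731 in SCR, and at 18S position 468, a target of SNORD83, with 0.624 and 0.791 against 0.806 and 0.821. At both of these positions the ADAR1 libraries differed from each other by more than either control differed from ADAR1 #2.

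With limma and Benjamini-Hochberg adjustment over the 110 positions, 0 passed an adjusted p of 0.05. The lowest adjusted p was 0.124, and 21 positions had an unadjusted p below 0.05 (17 higher and 4 lower). With calibrated p-values and no effect, 5.5 would be expected. In the simulation with no change and the moderated residual spread, 25% of runs gave a false adjusted call, more than calibrated p-values would give. Positions also share the same 5 libraries. The excess over 5.5, here and for ADAR2 below, is therefore no test against chance. At 28S position 3792 the difference was 0.0529 (95% interval 0.0302 to 0.0755). It was 0.0851 (0.0410 to 0.129) at 28S position 4590, and 28S position 3841 was lower, by -0.0596 (-0.0901 to -0.0291). These 3 positions and 28S position 4523 shared the lowest adjusted p of 0.124. At 28S position 3867 the difference was 0.136 (0.0387 to 0.233, adjusted p = 0.182). Over all positions the median width of the 95% interval on either side of the difference was 0.0323. When ADAR1 #1 was left out, 55 positions passed, and when ADAR1 #2 was left out, 28 passed. In those fits 1 ADAR1 library remained and the spread came from Mock and SCR alone. They compare single libraries and assume that each varies as Mock and SCR do. The calls without ADAR1 #1 included 18S position 354, where ADAR1 #2 and SCR were both listed at 0 and Mock at 0.0427. These counts are therefore not positions shown to differ from both controls.

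A size rule without a model gave 12 positions at which both ADAR1 libraries lay outside the reference values on the same side and their mean differed by at least 0.05. Without ADAR1 #1 the rule gave 20 positions. The 8 higher ones included, beside 28S positions 3867, 4590 and 3792 and 18S position 436, 28S position 2415 (0.592 ± 0.084, SD, n = 2, against 0.483 in Mock and 0.530 in SCR), 18S position 1804 (0.857 ± 0.055 against 0.790 and 0.807), 28S position 1881 (0.595 ± 0.030 against 0.536 and 0.545) and 28S position 2401 (0.881 ± 0.035 against 0.819 and 0.835). The 4 lower ones were 18S positions 468 and 627, 28S position 3841 (0.843 ± 0.0086 against 0.907 and 0.898) and 18S position 1447 (0.128 ± 0.022 against 0.163 and 0.193). At any size, both ADAR1 libraries lay outside the reference values on the same side at 55 positions (39 higher and 16 lower). Chance gives 33.3% of positions for 2 values against 2, or 36.7 positions. Smaller differences on the same side in both libraries were seen at 18S position 867 (0.0497) and 28S position 3724 (0.0472), and, on the lower side, at 28S positions 1524 (-0.0420), 2824 (-0.0310), 3744 (-0.0265) and 1625 (-0.0115) and 18S positions 1391 (-0.0298) and 1328 (-0.0252). None of these passed the limma test. Several differences depended on which ADAR1 library was used. Without ADAR1 #1 and without ADAR1 #2, respectively, they were 0.145 and 0.0267 at 28S position 2415, 0.0977 and 0.0198 at 18S position 1804, 0.0835 and 0.0159 at 18S position 867, 0.0785 and 0.0286 at 28S position 2401, 0.0757 and 0.0339 at 28S position 1881, 0.0223 and 0.0722 at 28S position 3724, -0.0410 and -0.0187 at 18S position 1391, -0.0686 and -0.233 at 18S position 627 and -0.0224 and -0.189 at 18S position 468.

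The second comparison asked the same of the single ADAR2 library. No position passed. The highest level relative to the reference was at 18S position 174, a target of SNORD45, with 0.724 in ADAR2 #1 against 0.497 in Mock and 0.493 in SCR. At the same position ADAR1 #2 was at 0.714 and ADAR1 #1 at 0.413. Other higher levels were at 28S position 2415 (0.599 against 0.483 and 0.530), 18S position 1804, a target of SNORD20 (0.887 against 0.790 and 0.807), 28S position 4306 (0.907 against 0.816 and 0.824) and 28S position 4590 (0.832 against 0.748 and 0.770). Lower levels were at 28S position 2861 (0.386 against 0.489 and 0.539), 28S position 400 (0.702 against 0.807 and 0.820), 28S position 4536 (0.773 against 0.881 and 0.869) and 28S position 4618 (0.511 against 0.587 and 0.601).

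In limma 0 of 110 positions passed, with a lowest adjusted p of 0.106 at 28S position 3792 (difference 0.0717, 95% interval 0.0439 to 0.0994), and 14 had an unadjusted p below 0.05 (8 higher and 6 lower) where chance gives 5.5. The difference at 18S position 174 was 0.228, with a 95% interval of -0.0686 to 0.525 because the 2 ADAR1 libraries, which contribute to the spread, lay far apart there. The single ADAR2 library was assumed to vary like the other groups. Fits of Mock, SCR and ADAR2 #1 alone, and fits without 1 ADAR1 library, took their spread from 1 pair of libraries. In the first of these the prior was infinite, so a fitted trend replaced each position's own spread. Its calls included 18S position 354, where ADAR2 #1 and SCR were both listed at 0 and Mock at 0.0427. Calls of these fits are thus not positions shown to differ from both controls. The size rule gave 19 positions outside the reference values by at least 0.05, 13 higher and 6 lower. Those not named above were, on the higher side, 18S position 436 (0.0765), 18S position 1440 (0.0839), 28S position 1323 (0.0718, but 0.0445 without Mock, below the limit, and 0.0991 without SCR), 28S position 3792, 5.8S position 14 (0.0669), 28S position 3701 (0.0637), 18S position 867 (0.0586) and 28S position 4637 (0.717 in ADAR2 #1 against 0.652 in Mock and 0.662 in SCR), and, on the lower side, 28S positions 2824 (-0.0573) and 3818 (-0.0557). Lower values of smaller size were at 28S positions 3724 (-0.0477), 1524 (-0.0450), 1760 (-0.0307) and 3760 (-0.0280). Across the 110 positions ADAR2 #1 lay outside the reference values at 91, where chance gives 66.7% for 1 value against 2, or 73.3 positions.

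**Figure D2:**
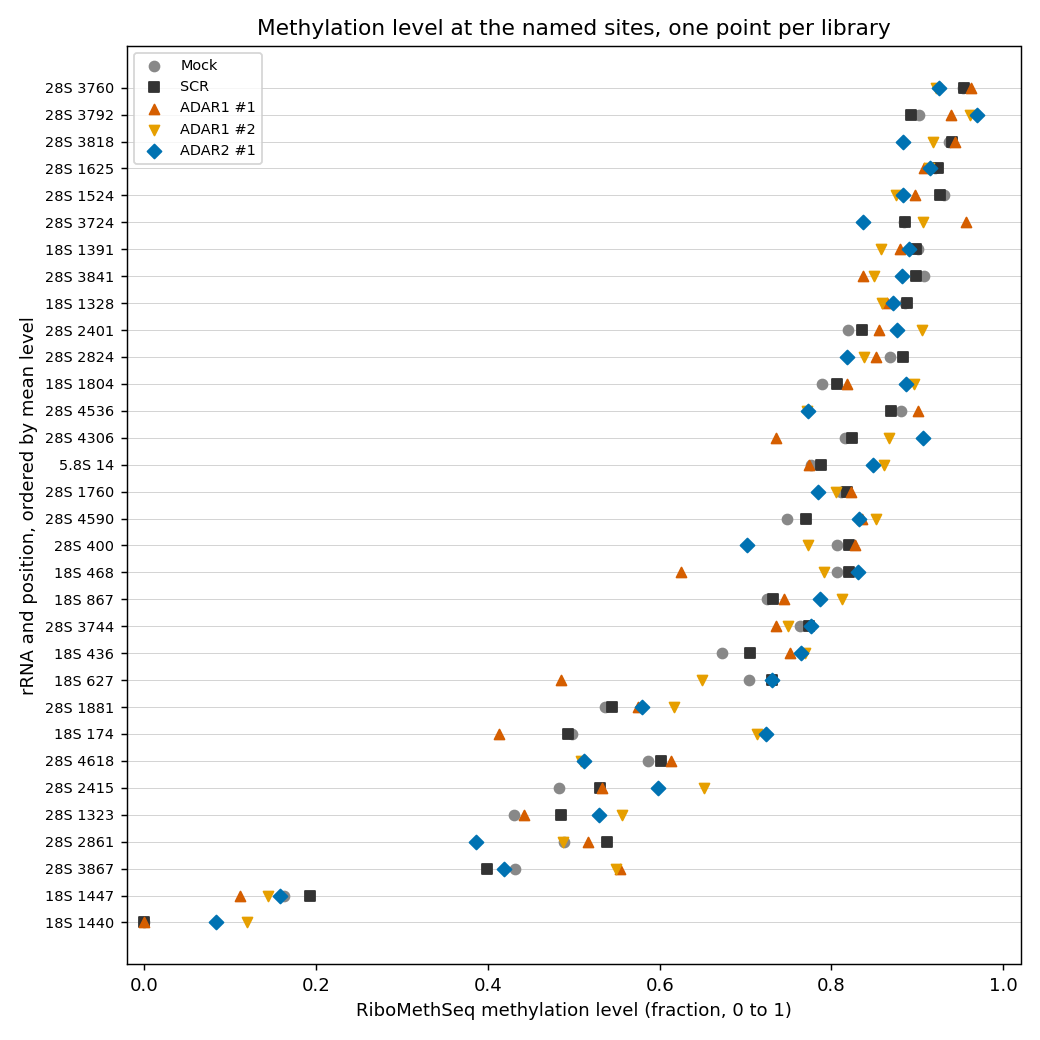
RiboMethSeq methylation level (fraction, x axis) at the positions named for the ADAR1 and ADAR2 comparisons (y axis, ordered by mean level), with 1 point per library. Mock and SCR lie close together at most positions, ADAR1 #2 and ADAR2 #1 lie together at 18S position 174 (0.714 and 0.724), and ADAR1 #1 lies apart at 18S positions 468 (0.624) and 627 (0.485).

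The third comparison set the ADAR1 libraries directly against ADAR2 #1. Again no position passed in limma. The lowest adjusted p was 0.528, and 9 positions had an unadjusted p below 0.05 (7 higher in ADAR1 and 2 lower). The largest differences were in both directions. ADAR1 was higher at 28S position 3867 (0.132, 95% interval 0.0135 to 0.251), 28S position 2861 (0.116, -0.0090 to 0.240), 18S position 354 (0.113, -0.152 to 0.378), 28S position 400 (0.0979, 0.0243 to 0.172) and 28S position 3724 (0.0949, 0.0397 to 0.150). Smaller positive differences were at 28S positions 3785 (0.0779), 4536 (0.0626), 4618 (0.0496), 3818 (0.0482) and 2876 (0.0436). ADAR1 was lower at 18S position 627 (-0.164, -0.337 to 0.0101), 18S position 174 (-0.160, -0.457 to 0.137), 18S position 468 (-0.123, -0.289 to 0.0424) and 28S position 4306 (-0.106, -0.237 to 0.0255). Smaller negative differences were at 28S positions 2365 (-0.0712), 3701 (-0.0565), 2422 (-0.0404), 3841 (-0.0389) and 3744 (-0.0338) and at 5.8S position 14 (-0.0312). Many of these differences rested largely on ADAR1 #1. Without ADAR1 #1 and without ADAR1 #2, respectively, the difference was -0.0101 and -0.310 at 18S position 174, 0 and 0.226 at 18S position 354, -0.0816 and -0.246 at 18S position 627, -0.0399 and -0.207 at 18S position 468, and -0.0396 and -0.172 at 28S position 4306. It was 0.0173 and 0.139 at 28S position 3785, -0.0113 and -0.131 at 28S position 2365, -0.0086 and -0.104 at 28S position 3701, and -0.0035 and -0.0773 at 28S position 2422. At 28S position 2876 the difference rested more on ADAR1 #2 (0.0672 and 0.01998). The difference changed sign at 28S position 4536 (-0.0019 and 0.127), 28S position 4618 (-0.0028 and 0.102) and 5.8S position 14 (0.0128 and -0.0753). At 28S position 3867 it was 0.1298 and 0.135. With ADAR1 #1 left out 13 positions passed, and with ADAR1 #2 left out 42 passed, each with the spread of Mock and SCR alone.

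Across the 110 positions, the differences of ADAR1 and of ADAR2 from the shared reference correlated with Pearson r = 0.434 and Spearman rho = 0.502, and had the same sign at 74 positions. Libraries simulated with no effect against the same reference gave a mean Pearson r of 0.403 (95% range 0.0032 to 0.690) and the same sign at 63.6% of positions, compared with 67.3% observed. The covariance was 0.000648 against 0.000312 simulated. All simulated libraries, Mock and SCR included, had the residual spread of each position, which holds the difference between the ADAR1 libraries. Mock and SCR differed less than the ADAR1 libraries did (root mean square 0.0155 and 0.0594). The simulated values may therefore overstate what the shared reference gives. The pooled value joined 2 unlike ADAR1 libraries: with ADAR1 #2 alone r was 0.825 (rho 0.762), and with ADAR1 #1 alone it was -0.122 (rho 0.0629). The reference could be divided only into single libraries. With separate reference libraries r was 0.776 or 0.773 for ADAR1 #2, and -0.0880 or -0.197 for ADAR1 #1. The shared controls therefore do not account for the high value of ADAR1 #2. With the ADAR1 mean set against Mock and ADAR2 against SCR r was 0.443, and with the reverse it was 0.328. Positions are not independent replicates, so no p-value is attached. At 5 positions (18S positions 436 and 1804 and 28S positions 2415, 3792 and 4590) both comparisons met the size rule in the same direction, and at 0 positions did they meet it in opposite directions. Both counts use the same reference libraries, which alone raises the first.

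**Figure D3:**
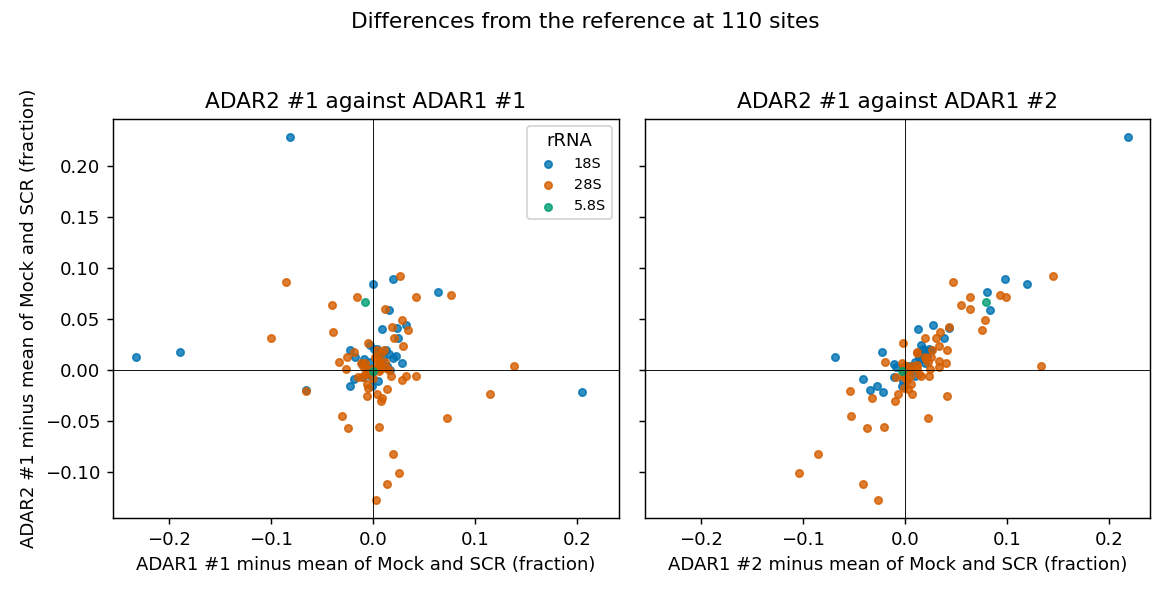
Difference of ADAR2 #1 from the mean of Mock and SCR (y axis, fraction) against that of ADAR1 #1 (left) and ADAR1 #2 (right), with 1 point per rRNA position coloured by rRNA. The points follow a rising line for ADAR1 #2 (r = 0.825) and do not for ADAR1 #1 (r = -0.122).

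The overall level of methylation was compared as the mean over all 110 positions. It was 0.823 in Mock, 0.828 in SCR, 0.827 in ADAR1 #1, 0.842 in ADAR1 #2 and 0.834 in ADAR2 #1. The ADAR1 mean exceeded the reference mean by 0.0093, less than the SD of the 2 ADAR1 library means (0.0106), and the ADAR2 library exceeded it by 0.0092. Without ADAR1 #1 the ADAR1 difference was 0.0168, and without ADAR1 #2 it was 0.0018. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, so none was run.

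No list of positions fixed before the data were examined passed a test as a group. Over all 110 positions, 70 were higher and 40 lower in ADAR1, and 72 higher and 38 lower in ADAR2 #1. For ADAR1 against ADAR2, 55 were higher and 55 lower. SCR was higher than Mock at 67 positions. The counts within lists are to be read beside these. The 41 positions of 18S had 0 members past the threshold in the ADAR1 comparison, 29 with a higher and 12 with a lower ADAR1 mean, and 32 higher and 9 lower in ADAR2 #1, also with 0 past it. The mean level over 18S was 0.813 in Mock, 0.818 in SCR, 0.813 in ADAR1 #1, 0.835 in ADAR1 #2 and 0.837 in ADAR2 #1. The 67 positions of 28S had 40 higher and 27 lower in ADAR1 and 39 higher and 28 lower in ADAR2 #1, with means of 0.828, 0.833, 0.835, 0.845 and 0.832 in the same order of libraries. Camera with a preset correlation gave 18S against the other positions an adjusted p of 0.861 in ADAR1 and 0.0632 in ADAR2 #1. With an estimated correlation the ADAR2 value was adjusted p = 0.786. Of the 5.8S positions, position 14 (a target of SNORD71) was at 0.776 in Mock, 0.787 in SCR, 0.773 in ADAR1 #1, 0.861 in ADAR1 #2 and 0.849 in ADAR2 #1. Position 75 (a target of SNORD96) stayed between 0.903 and 0.909 in the 5 libraries.

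The 26 partly methylated positions (mean level below 0.8) averaged 0.586 in Mock, 0.598 in SCR, 0.595 in ADAR1 #1, 0.626 in ADAR1 #2 and 0.609 in ADAR2 #1. Of these, 18 had a higher and 8 a lower ADAR1 mean, and 0 passed. Their either-direction test by fry gave an adjusted p of 0.1102, the lowest such value of the 10 lists tested in that comparison. The mean difference of this list in ADAR1 was positive (0.0185), while camera, which compares the list with the other positions, gave it the direction down (adjusted p = 0.933). The 17 fully methylated positions (mean level of at least 0.95) averaged between 0.958 and 0.963 in all libraries. The 42 positions with another listed position within 6 nucleotides and the 68 isolated ones gave adjusted p-values of 0.861 each by camera in ADAR1 and 0.522 each in ADAR2 #1. In the 5′ part of 18S (27 positions, the last at 867) 21 positions were higher and 6 lower in both comparisons. In its 3′ part (14 positions) 8 were higher in ADAR1 and 11 in ADAR2 #1. In the 5′ part of 28S (21 positions up to 2500) 9 were higher and 12 lower in ADAR1, with a mean difference of 0.0073 and a median of -0.0009. That mean difference was -0.0050 in ADAR1 #1 and 0.0196 in ADAR1 #2. In ADAR2 #1, 14 positions of the 5′ part of 28S were higher and 7 lower. In the 3′ part of 28S (46 positions) 31 were higher in ADAR1 and 25 in ADAR2 #1, where the mean difference was -0.0013 and the median 0.0020. Adjusted over the list alone, only 28S position 3792 passed in limma, in the 3′ part of 28S for ADAR2 #1 (adjusted p = 0.0441), and it did not pass over all 110 positions. In the direct comparison of ADAR1 with ADAR2 no list passed either, and adjusted over the list alone no position did. There 18S had 13 positions higher in ADAR1 and 28 lower, and 28S had 42 higher and 25 lower, while the 3′ part of 18S had 2 higher and 12 lower and that of 28S 31 higher and 15 lower. These 4 lists shared the lowest adjusted p by camera of the 10 tested, 0.109, which was 0.842 with an estimated correlation.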

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

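The direct test of ADAR1 against ADAR2 was planned, while the positions given here were selected on the same data and leaving out ADAR1 libraries at all of them was added after seeing it. At 11 positions both ADAR1 libraries lay on one side of the Mock and SCR values and ADAR2 #1 lay on the other, where chance gives 6.67% of positions, or 7.33. The difference of ADAR1 minus ADAR2 was -0.123 at 18S position 468, -0.0165 at 18S position 1703, 0.0268 at 28S position 398, -0.0147 at 28S position 2351, 0.0287 at 28S position 2787, 0.0264 at 28S position 2815, 0.0949 at 28S position 3724, -0.0338 at 28S position 3744, 0.0252 at 28S position 4370, 0.029998 at 28S position 4494 and 0.0290 at 28S position 4498. Without ADAR1 #1 and without ADAR1 #2, respectively, the value was -0.0399 and -0.207 at 18S position 468, 0.0120 and 0.0385 at 28S position 4370 and 0.0106 and 0.0474 at 28S position 4498. None passed the direct limma test of ADAR1 against ADAR2, whose adjusted p ranged from 0.528 to 0.774 over these positions. At 28S position 3724, which had the lowest unadjusted p of them (0.0063), the levels were 0.884 in Mock, 0.886 in SCR, 0.957 in ADAR1 #1, 0.907 in ADAR1 #2 and 0.837 in ADAR2 #1.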

How the results depend on the processing

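The fits of 1 ADAR1 library at a time against Mock and SCR alone were added after seeing the data, as was counting the planned fry tests beside camera, and the other alternatives were planned. No paired analysis was possible, because Mock and SCR carry no number and the meaning of the #1 shared by ADAR1 and ADAR2 is not given. The 3 limma counts stayed at 0 with no variance trend, the logit, a robust trend, median-centred libraries (lowest adjusted p 0.0769 for ADAR1 and 0.0726 for ADAR2), positions with a mean of at least 0.5 and an adjusted p of 0.1, and without Mock or SCR. Leaving out libraries gave 0 to 55 positions for ADAR1, 0 to 38 for ADAR2 and 0 to 42 for ADAR1 against ADAR2, and the compared groups only gave 0 for ADAR1 and 37 for ADAR2. ADAR1 #1 alone against Mock and SCR gave 28 and ADAR1 #2 alone 56. Where counts were higher, the residual spread no longer held the difference between the 2 ADAR1 libraries, as these fits are built. In the fits of 1 ADAR library against Mock and SCR alone, the prior was also infinite. A fitted trend then replaced each position's own spread, and calls included 18S position 354 for ADAR1 #2 and for ADAR2 #1. There both were listed at 0, as was SCR, so these counts do not give positions that differ from both controls. The size rule gave 3 (ADAR1) and 4 (ADAR2) positions at a limit of 0.1, and 32 and 42 at 0.02. Leaving out libraries gave 11 to 20 for ADAR1. The mean difference over all positions was 0.0018 to 0.0168 for ADAR1 and 0.0066 to 0.0117 for ADAR2 when libraries were left out, and no list passed camera or fry under any setting run. The correlation of effects ranged from -0.122 (without ADAR1 #2) to 0.825 (without ADAR1 #1). For the upper value, the tests run argued against a shared reference, a few large differences and a level-dependent shift. They argued against coverage shared with listed neighbours within 6 nucleotides only as the whole cause, and exchanged labels stayed open. Among the 81 differences followed at named positions, the logit reversed 0, while among all 18S positions it moved the ADAR1 minus ADAR2 signs from 13 higher and 28 lower to 15 and 26. When each library was left out in turn, the ADAR1 difference ranged from -0.0214 to 0.204 at 18S position 354, from -0.0368 to 0.0126 at 28S position 2861, from -0.0158 to 0.0989 at 28S position 1323, from -0.0124 to 0.0342 at 18S position 428, from -0.0084 to 0.0796 at 5.8S position 14 and from -0.0047 to 0.0013 at 5.8S position 75. The ADAR2 difference ranged from -0.0130 to 0.0197 at 28S position 3867 and from -0.0045 to 0.00145 at 5.8S position 75. ADAR1 minus ADAR2 ranged from -0.0019 to 0.127 at 28S position 4536, from -0.0028 to 0.102 at 28S position 4618, from -0.0753 to 0.0128 at 5.8S position 14, from -0.0839 to 0.0360 at 18S position 1440, from -0.0876 to 0.0271 at 28S position 1323, from -0.0652 to 0.0530 at 28S position 2415 and from -0.0012 to 0.00098 at 5.8S position 75. Unknown depth limits all of these values.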

Other observations

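Among the tests below, those of the shared reference, of exchanged labels, of a common effect of both genes and both of a few large differences were chosen after the result was seen. The fit of all 3 ADAR libraries together and the selection of positions by groups of libraries were also chosen after the data were seen.

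ADAR1 #2 was the highest of the 5 libraries at 42 positions and the lowest at 9. These counts were 21 and 21 for ADAR2 #1, 7 and 31 for Mock and 15 and 18 for SCR. ADAR1 #1 was the highest at 25 positions and the lowest at 29, where chance gives each library 44 in all. Among its larger gaps from the other 4 libraries, its level was lower at 18S position 468 (0.624 against 0.791 to 0.831), 18S position 627 (0.485 against 0.649 to 0.731), 28S position 2365 (0.761 against 0.860 to 0.892) and 28S position 4306 (0.735 against 0.816 to 0.907). It was higher at 18S position 354 (0.226 against 0 to 0.0427), 28S position 3785 (0.857 against 0.719 to 0.744) and 28S position 4498 (0.834 against 0.787 to 0.797). ADAR1 #2 and ADAR2 #1 both lay above the other 3 libraries at 40 positions and below them at 10, where chance gives 22 in all. Wide gaps were at 18S position 174 (0.714 and 0.724 against 0.413 to 0.497), 28S position 4536 (0.771 and 0.773 against 0.869 to 0.9002), 28S position 4618 (0.509 and 0.511 against 0.587 to 0.614), 18S position 1804 (0.896 and 0.887 against 0.790 to 0.818) and 5.8S position 14 (0.861 and 0.849 against 0.773 to 0.787).

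ADAR1 #2 and ADAR2 #1, which carry different gene labels, differed from the reference alike (r = 0.825 across positions). ADAR1 #1 and ADAR1 #2 did so far less (r = 0.193, and 0.238 or 0.0958 with separate reference libraries). The rank correlation of these 2 was 0.295, and their sign was the same at 72 of 110 positions. Libraries simulated with no effect and a shared reference gave a mean r of 0.326 (range -0.0892 to 0.651). There Mock and SCR had the residual spread of each position, so 0.326 may overstate what the shared reference gives. Whether 0.193 exceeds the share of the reference was therefore not settled. The shared reference does not account for the likeness of ADAR1 #2 and ADAR2 #1, since separate reference libraries left r at 0.773 or above. Neither do a few large differences, since the rank correlation was 0.762. Removing a library-wide shift that depends on the level of a position left a residual r of 0.828. For coverage shared between neighbours, r was -0.0502 over 27 close pairs in ADAR1 #2. The range of shuffled positions (-0.354 to 0.375) is wide, so moderate sharing cannot be excluded. Over 68 isolated positions r was 0.804, which argues against listed neighbours within 6 nucleotides as the whole cause. Coverage shared over longer stretches was not tested. A common effect of both genes may be one explanation, but ADAR1 #1 correlated with ADAR2 #1 at r = -0.122. Their rank correlation was 0.0629, and the sign was the same at 64 of 110 positions. This 1 library cannot exclude a common effect, for instance if #1 and #2 are different reagents. An exchange of the labels of ADAR1 #1 and ADAR2 #1 cannot be told apart from it, because the table holds no expression of the 2 genes, and an unrecorded batch stays open as well.

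ADAR1 #1 and ADAR1 #2 differed 3.82 times as much as Mock and SCR by root mean square. The bounded scale of the score is argued against as the whole cause, because the ratio was 3.01 on the logit scale, and so are a few large differences, because the ratio of median absolute differences was 2.69. A difference in read depth could give such a ratio of 3.82 and was not testable without read counts. A biological difference between the 2 ADAR1 libraries, such as different reagents, was not tested.

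All 3 ADAR-labelled libraries lay on the same side of both Mock and SCR at 40 positions, 30 higher and 10 lower, where chance gives 20%, or 22 positions. Fitting the 3 together against Mock and SCR in limma gave 0 positions at an adjusted p of 0.05 and 19 at an unadjusted p of 0.05. The lowest adjusted p, 0.0598, was shared by 28S position 3792 (difference 0.0591, SE 0.0096), 28S position 4523 (0.0274, SE 0.0050) and 28S position 4590 (0.0813, SE 0.0150), each higher in 3 of 3 libraries. At 28S position 1524 the level was lower in 3 of 3 libraries (-0.0430, SE 0.0091), with the same adjusted p of 0.0881 as the higher level at 18S position 683 (0.0361, SE 0.0080), and at 18S position 436 the smallest of the 3 differences was 0.0636. Of the 10 splits of the 5 libraries into 3 and 2, 2 gave as many positions fully to one side. The real split gave 40 and the highest other gave 50, and 10 splits are too few for a share under 0.05. That other split set ADAR1 #2 and ADAR2 #1, the pair closest after Mock and SCR, against the rest, and gave 5 positions in limma with a lowest adjusted p of 0.0073. It was the most extreme of the 10, so these calls restate the likeness of that pair and are no separate test of it.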
